A study of Mus musculus with 4 samples.

How the data were processed

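Satellite cells, the resident stem cells of skeletal muscle, were compared between young and aged C57BL/6 mice on Affymetrix expression arrays. Per the labels, young mice were 3 to 6 months old and aged mice 20 to 25 months old, cells of several mice were pooled and sorted for the surface proteoglycan syndecan-4, and each array holds the RNA of 1 pool. The series text gives 4 to 8 mice per pool and the sample text 6 to 8. There were 2 independent pools per age, so 4 arrays in all. Per the labels' protocols, the RNA went through 2 rounds of linear T7 amplification before biotin labelling.

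The values used are those deposited by the authors in 1 table of 45101 probe sets, taken here as log2 values. They lie on both sides of 0, and the median of every probe set over the 4 arrays is 0 within 5e-07, so each value is relative to that median. Centring leaves the difference between ages of a probe set as it was, but it removes the absolute level. No probe set can therefore be called bright, dim or absent, and no level can be set against another. The base of the logarithm, the background correction, the summary of probes and the normalization between arrays are not given in the sources used here. If the base were not 2, every fold printed here would change, while directions and p-values would not. The direction of the values (higher means more RNA) is likewise an assumption. The array medians were -0.07 for young 1, 0.03 for young 2, -0.01 for aged 1 and 0.05 for aged 2. The array means lay within 0.0199 of each other. The upper quartiles differed by up to 0.161, above the planned limit of 0.1 for leaving values as deposited. That limit was written for uncentred values, so the deposited values were kept and quantile normalization was run as an alternative.

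Probe sets were named from the platform annotation, with symbols updated by Entrez ID to the names of the GRCm38.p6 reference where possible (34741 probe sets matched). Of the probe sets that are no controls, 34945 carried 1 gene symbol, 932 carried several and 9160 had none. Those with several or none were left out of gene tests, as were 64 control probe sets. A gene's value was the mean of its probe sets, which gave 18193 genes, 9183 of them with 1 probe set. Listed symbols that are current names of other genes were never matched as synonyms.

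Aged and young pools were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, coefficient aged minus young), with Benjamini-Hochberg adjustment over all 18193 genes and a threshold of 0.05. The 2 residual degrees of freedom were supplemented by eBayes with 3.56 prior degrees of freedom. The ± after a log2 difference is the standard error of that fit (n = 2 pools per age). Tests of single genes rest on the spread between pools, and the mice within a pool are averaged. Figures were drawn with matplotlib 3.10.9.

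The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The centred unit forced several departures. The probe set with the highest mean could not be chosen, so the mean over probe sets, planned for comparison, was used. A variance trend on mean expression (trend = TRUE) had been planned, but the mean of centred values is no expression level. In data simulated with no changed gene, the trend called a mean of 62.95 genes and at most 90, against a mean of 0.2 without it. The fit without trend was therefore made the main one, and the fit with trend is given as an alternative. A filter on dim genes, log2 offsets and the condition on a named gene's level could not be applied.

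The pipeline was tested on simulated data, with 200 of 18193 genes changed in each of 20 simulations. It called a share of 0.005 of genes changed by a log2 of 1, 0.234 of those changed by 2, 0.863 of those changed by 3 and 0.979 of those changed by 4. The mean share of false calls was 0.0761. The simulated variances were drawn from those already shrunk by eBayes, with independent normal errors, so these shares are likely too high for the real arrays. In the data even Xist, with a log2 difference of 6.16, was not called. An absence of calls therefore does not mean that no gene changed by a log2 of 4.

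Of 35 gene lists (25 of pathways and processes, 10 of cell type markers), 34 with at least 5 measured genes were tested with camera from limma, at a preset correlation between genes of 0.01 and with adjustment over all lists. Camera asks whether a list shifts relative to all other genes. At the preset correlation its p-value rests on the spread across genes, which are no independent replicates. Such a p-value does not measure the spread between pools. Camera with an estimated correlation, which has 2 degrees of freedom behind each estimate, camera on ranks and fry were alternatives. With an estimated correlation the p-value itself also rests on 2 degrees of freedom, so a call over 34 lists was hard to reach. A call lost there does not show that correlation between genes explains the shift. The phrase "adjusted over the list alone" means Benjamini-Hochberg over a list's members.

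Genes were named by 3 rules. The first takes, per direction, the 12 genes with the largest difference among those past the threshold, filled where too few pass with genes of an unadjusted p under 0.01, always with both aged pools on the same side of both young pools. The second takes up to 4 members with the smallest p of each list discussed. The third always names a fixed set of muscle stem cell, p38, FGF receptor, JAK-STAT, Notch and CDK inhibitor genes together with Xist and Acta1. A gene named outside these rules is said to have been chosen after its values were seen.

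Arrays of both ages carry the numbers 1 and 2 in the labels. No label says that a number marks a shared day or batch, so the model has no block. The added hybridization controls bioB, bioC and bioD split the arrays by this number, so values within each number are printed beside the shifts of the called lists. Alternatives were quantile normalization, a common median, probe sets ending in _x_at or _s_at left out, the replicate number as a block, each pool left out, all probe sets, other thresholds, a minimum fold of 1.2 (treat) and array weights. After the data were seen, the probe set with the largest SD was added as an alternative, as was a set test with the genes of fibres and energy metabolism left out of all other lists. No other list held any of these genes, so that test changed only the genes that a list was compared against.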

Results

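Gene expression was measured in syndecan-4-sorted satellite cells from the hindlimb muscle of young and aged mice, with 2 pools of mice per age and 1 array per pool. The series title places the comparison in work on p38 signalling and the loss of self-renewal in aged muscle stem cells. Values are taken as log2 (the base was not stated) and are relative to each probe set's median over the 4 arrays, so differences between ages are given and no levels. Along the first principal component of the genes, which carried 45.5% of the variance, the young pools lay at -64.9 and -40.2 and the aged pools at 42.8 and 62.3. The second, with 31.5%, parted the pools by number. Young 1 and aged 1 lay at -20.3 and -63.4 on it, young 2 and aged 2 at 37.2 and 46.5. The root mean square difference over genes was 0.841 between the young pools and 0.911 between the aged pools, against 0.964 to 1.07 between pools of different age.

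Markers of mature muscle fibres were lower in aged cells in 24 of 24 cases, while Xist and several T cell and chemokine transcripts were among those higher in aged cells. Alpk3, a kinase of striated muscle, was 39.2-fold lower (log2 difference -5.29 ± 0.36, adjusted p = 0.0998 with limma). Xist, the RNA that silences an X chromosome in female cells, was 71.7-fold higher (6.16 ± 0.44, adjusted p = 0.0998). With limma, 0 of 18193 genes passed the adjusted threshold of 0.05. At an adjusted p under 0.10 there were 6 genes higher and 33 lower in aged cells. At an unadjusted p under 0.05 there were 1645 genes, 518 higher and 1127 lower, where chance alone gives 910. Of the 586 genes with an unadjusted p under 0.01, all at least 2-fold apart, 113 were higher and 473 lower. The ages did not overlap in 36.8% of genes, where chance gives 33.3%. Fitted with the variance trend that had been planned, limma called 221 genes, 26 higher and 195 lower, but that fit also called genes in simulated data with no change. Without young replicate 1 the 473 lower genes became 177, without young replicate 2 they became 312 and without aged replicate 2 they became 266, and the 113 higher genes became 61 and 46 without young replicate 1 and young replicate 2.

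**Figure D1:**
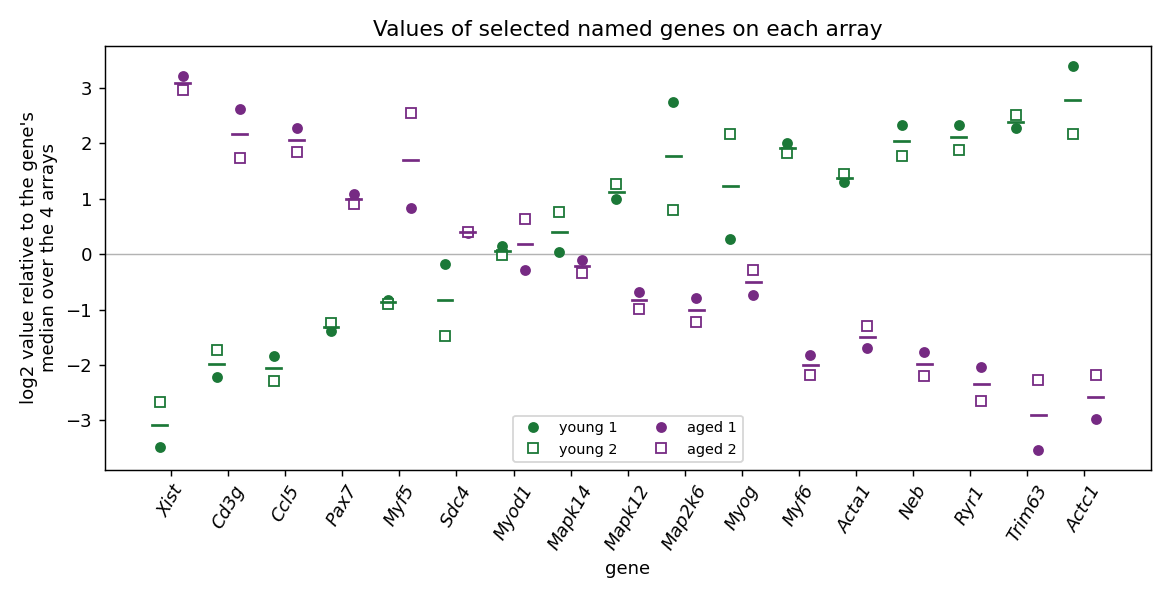
Log2 value of 17 named genes (vertical axis, relative to the gene's median over the 4 arrays) on each array, with young pools in green, aged pools in purple, filled circles for pools numbered 1, open squares for pools numbered 2 and a short line at each age's mean. The aged pools lie above both young pools for Xist, Cd3g, Ccl5, Pax7, Myf5 and Sdc4, the ages overlap for Myod1, and the young pools lie above for Mapk14, Mapk12 and the genes to their right.

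None of the genes named by size passed the adjusted threshold. Among genes with an unadjusted p under 0.01, the 12 with the largest negative differences were, beside Alpk3, Actc1, the cardiac alpha-actin (-5.36 ± 0.56), the muscle ubiquitin ligase Trim63 (-5.30 ± 0.52), Dusp23 (-4.84 ± 0.61), the muscle cytochrome oxidase subunit Cox8b (-4.68 ± 0.44), the thin filament protein Tmod4 (-4.60 ± 0.40), the Z-disc protein Myoz1 (-4.55 ± 0.49), Ttll7 (-4.55 ± 0.56), the calcium release channel Ryr1 (-4.45 ± 0.42), Abra (-4.39 ± 0.68), Lmod2 (-4.35 ± 0.39) and Asb15 (-4.33 ± 0.44). Their adjusted p-values ran from 0.0998 to 0.150. The 12 with the largest positive differences at that p were Xist, Akr1c14 (4.28 ± 0.71), the immunoglobulin joining chain Jchain (4.28 ± 0.58), the claudin Cldn11 (4.22 ± 0.56), the T cell receptor subunits Cd3g (4.15 ± 0.47) and Cd3d (4.11 ± 0.50), the chemokine Ccl5 (4.12 ± 0.40), Gm8369 (4.10 ± 0.48), the chemokine Cxcl3 (3.68 ± 0.90), Zdhhc13 (3.58 ± 0.48), Vps33b (3.46 ± 0.45) and Ctla2a (3.35 ± 0.36). Their adjusted p-values ran from 0.0998 to 0.288. The 3 probe sets of Xist differed by 6.09, 5.76 and 6.64.

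Markers of mature fibres fell together in aged cells. All 24 measured members of this list were lower, with a median log2 difference of -2.83 (7.13-fold; -2.70 between pools numbered 1 and -2.74 between pools numbered 2). With limma, 23 of the 24 passed when adjusted over the list alone and 0 when adjusted over all genes. The calcium release channel Ryr1 and the Z-disc protein Myoz1 stood beside the giant thin filament protein Neb (-4.03 ± 0.41) and the fast fibre actinin Actn3 (-2.97 ± 0.38). Acta1, the skeletal muscle actin, was 7.32-fold lower (-2.87 ± 0.38, adjusted p = 0.117). Camera gave an adjusted p of 2.37e-31, and adjusted p = 0.191 with an estimated correlation. That estimate was -0.032, below the preset 0.01, so correlation between members does not account for the higher p.

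Genes of oxidative phosphorylation and of glycolysis also fell as lists, beside the lower fibre markers. Whether they fell through less fibre RNA in the aged pools was not tested. Of 36 measured oxidative phosphorylation genes, 35 were lower, with a median of -1.36 (2.56-fold; -1.24 and -1.23 within numbers 1 and 2), and 5 passed adjusted over the list alone. Among them were the complex I subunits Ndufc1 (-2.65 ± 0.40) and Ndufa5 (-2.28 ± 0.42), the succinate dehydrogenase subunit Sdhb (-2.20 ± 0.35) and the ATP synthase subunit Atp5o (-2.43 ± 0.40). Camera gave an adjusted p of 3.38e-18, and adjusted p = 0.312 with an estimated correlation. In the glycolysis list 13 of 19 members were lower, with a median of -1.20 (-0.90 and -1.59 within numbers 1 and 2), and adjusted over the list alone 8 lower members and 1 higher member passed. The lower members included the muscle isoenzymes Eno3 (-4.23 ± 0.53) and Pgam2 (-2.64 ± 0.36), the pyruvate kinase Pkm (-2.74 ± 0.37) and the aldolase Aldoa (-2.09 ± 0.36). Camera gave an adjusted p of 6.07e-05 for glycolysis, and adjusted p = 0.312 with an estimated correlation.

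The proteasome and ubiquitin list fell, with 25 of 28 members lower and a median of -0.64 (-0.59 and -0.77 within numbers 1 and 2; camera adjusted p = 2.91e-07; adjusted p = 0.312 with an estimated correlation). Its extremes were the atrophy-linked ubiquitin ligases Trim63 and Fbxo32 (-2.78 ± 0.45), which are enriched in muscle fibres, and it held the proteasome ATPases Psmc2 (-1.91 ± 0.45) and Psmc3 (-1.53 ± 0.37). Adjusted over the list alone, 4 members passed, all lower. The median was -1.08 without aged replicate 1 and -1.26 with the probe set with the largest SD.

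Genes of myogenic commitment and differentiation fell as a list but moved both ways as members. Of 29 measured, 18 were lower and 11 higher, with a median of -0.49 (-0.73 and -0.62 within numbers 1 and 2), and 6 passed adjusted over the list alone, all lower. The regulator Myf6, which is most abundant in mature muscle, was 15.2-fold lower (-3.92 ± 0.37, adjusted p = 0.0998). Actc1, the thin filament nucleator Lmod3 (-3.07 ± 0.51) and the myosin light chain Myl1 (-2.10 ± 0.37) were also lower. Myog, a driver of terminal differentiation, stood at -1.74 ± 0.68 (adjusted p = 0.540; -0.79 without young replicate 2 and -2.69 without young replicate 1), and Myod1, a marker of activated myoblasts, at 0.12 ± 0.45 with overlapping ages and 1 probe set in each direction. Camera gave an adjusted p of 0.0106 for this list, adjusted p = 0.312 with an estimated correlation and 0.169 on ranks, and the call was lost without aged replicate 1 (median -0.18, adjusted p = 0.119). The median was -1.22 with the probe set with the largest SD and -0.86 over members held by no other list.

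Among regulators of the satellite cell itself, Pax7, the transcription factor that marks these cells, was 4.94-fold higher in aged cells (2.31 ± 0.36, adjusted p = 0.150). Its 2 probe sets differed by 3.51 and 1.10. Myf5 was 5.88-fold higher (2.56 ± 0.63, adjusted p = 0.288; 1.69 without aged replicate 2) and syndecan-4, the protein used for the sort, had an Sdc4 difference of 1.22 ± 0.53 (adjusted p = 0.593; 0.57 without young replicate 2 and 1.87 without young replicate 1). Whether a smaller share of fibre RNA in the aged pools raised Pax7, Myf5 and Sdc4 was not tested. Of 29 measured genes of satellite cell identity and quiescence, 18 were higher and 11 lower, and 1, Pax7, passed adjusted over the list alone. The median was 0.10 (0.20 and 0.29 within numbers 1 and 2; 0.28 without young replicate 1 and 0.17 without probe sets ending in _x_at or _s_at) and the mean 0.39. Camera did not call this list (adjusted p = 0.0666), but called it higher without probe sets ending in _x_at or _s_at (0.0328) and without young replicate 1 (0.0485), and its adjusted p was 0.0652 to 0.365 under the other settings run. The surface markers Cd34 (-0.29 ± 0.43), Vcam1 (-0.15 ± 0.42) and Sdc3 (-0.21 ± 0.39), and the FGF inhibitor Spry1 (-0.26 ± 0.54), differed by less than their standard error. The 3 probe sets of Sdc3 ran from -1.70 to 0.55.

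The p38 MAPK list, the pathway named by the series title, fell by a small amount, with 25 of 34 members lower and a median of -0.21 (camera adjusted p = 0.0376; adjusted p = 0.312 with an estimated correlation). Within pools numbered 1 and 2 the medians were -0.34 and -0.07. None of its members passed adjusted over the list alone. Whether the falls in this list came from less fibre RNA in the aged pools was not tested. The smallest p-values among its lower members were those of p38 gamma, Mapk12, an isoform enriched in skeletal muscle (-1.96 ± 0.37), its activating kinase Map2k6 (-2.78 ± 0.70), the chromatin remodelling subunit Smarcd3 (-2.51 ± 0.64) and the upstream kinase Map3k7 (-1.10 ± 0.38). The alpha and beta isoforms Mapk14 (-0.62 ± 0.42) and Mapk11 (-0.25 ± 0.40), and the activating kinase Map2k3 (-0.24 ± 0.38), had differences under 1.5 standard errors. The 6 probe sets of Mapk14 ran from -2.04 to 0.63. The call was lost without young replicate 1 (adjusted p = 0.316), without aged replicate 1 (0.162) and without aged replicate 2 (0.0604), and with the probe set with the largest SD (0.0813). The median was -0.14 without aged replicate 1 and -0.43 with the probe set with the largest SD. Without young replicate 1 Map2k6 stood at -1.81 and Mapk14 at -0.98, without young replicate 2 Mapk14 stood at -0.27, and Map2k3 stood at -0.47 and -0.02 without aged replicate 1 and aged replicate 2.

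The receptors and inhibitors fixed beforehand showed small differences, with no adjusted p under 0.58. Fgfr1 stood at 0.48 ± 0.40 and Fgfr4 at 0.33 ± 0.39. Jak2 stood at -0.09 ± 0.42, Stat3 at 0.26 ± 0.59 and Socs3, a feedback inhibitor of JAK-STAT signalling, at 0.39 ± 0.50. Notch1 stood at -0.51 ± 0.44 and Notch3 at 0.88 ± 0.38. The cell cycle inhibitors Cdkn2a (-0.67 ± 0.73), Cdkn1a (-0.46 ± 0.36) and Cdkn1b (0.17 ± 0.74) gave no difference beyond 1.5 standard errors. Without 1 pool the values ran from 0.19 to 0.78 for Fgfr1, from 0.12 to 0.55 for Fgfr4 and from -0.91 to -0.11 for Notch1.

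**Figure D2:**
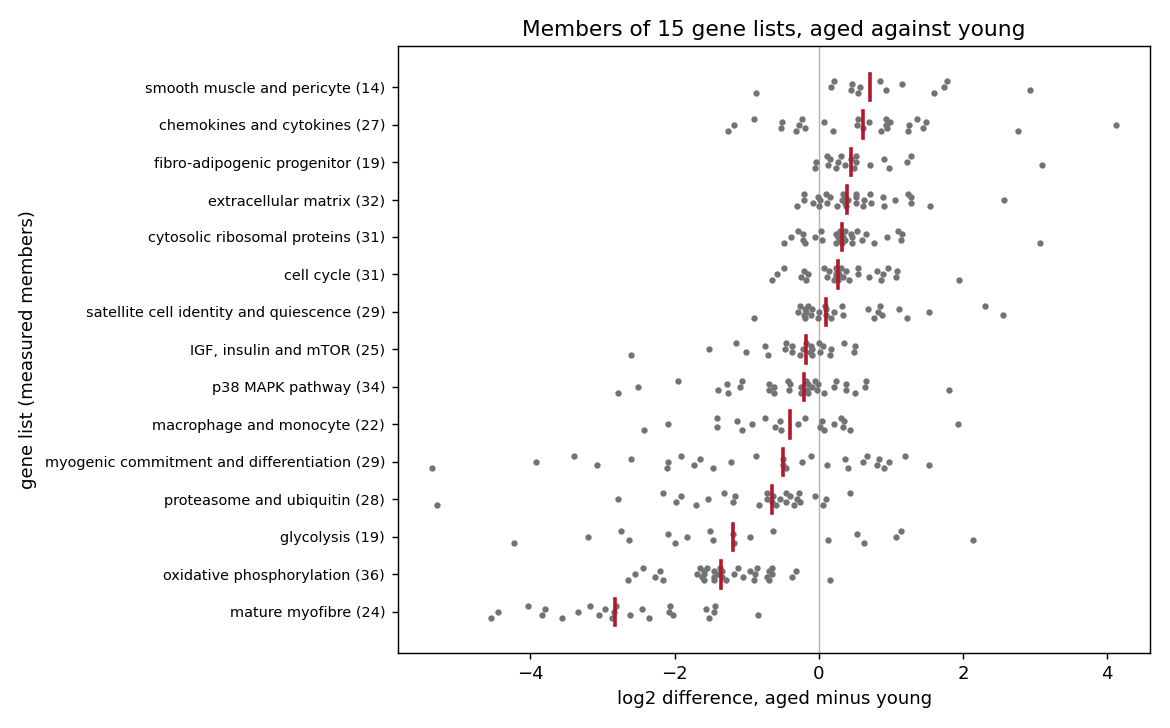
Log2 difference, aged minus young, of each measured member (grey points, n = 2 pools per age) of the 14 lists that camera called and of the satellite cell identity list, with the list's median as a red line and the number of measured members in brackets; vertical offsets within a list only separate points. The mature myofibre list lies farthest left with a median of -2.83, and the smooth muscle and pericyte list farthest right with a median of 0.71.

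Markers of several stromal cell types rose as lists in aged cells. Smooth muscle and pericyte markers were higher in 13 of 14 cases, with a median of 0.71 (1.04 and 0.62 within numbers 1 and 2; camera adjusted p = 0.0032; adjusted p = 0.312 with an estimated correlation). The pericyte genes Rgs5 (2.93 ± 0.58), Kcnj8 (1.78 ± 0.69), Higd1b (1.74 ± 0.51) and Cspg4 (0.94 ± 0.39) had the smallest p-values, and Rgs5 alone passed adjusted over the list alone. Fibro-adipogenic progenitor markers were higher in 17 of 19 cases, with a median of 0.44 (0.44 within either number; camera adjusted p = 0.0090; adjusted p = 0.312 with an estimated correlation). Mgp stood at 3.10 ± 0.94, Lum at 1.28 ± 0.65, Gsn at 0.97 ± 0.46 and Dcn at 0.90 ± 0.39. Extracellular matrix genes were higher in 26 of 32 cases, with a median of 0.39 (0.42 and 0.24 within numbers 1 and 2), among them Postn (2.57 ± 0.82), Bgn (1.54 ± 0.50) and the laminin chain Lama2 (1.24 ± 0.43), and their camera adjusted p was 0.0032, with adjusted p = 0.312 with an estimated correlation. No member of the progenitor and matrix lists passed adjusted over the list alone. Without aged replicate 1, the pericyte and matrix calls were lost, each with an adjusted p of 0.0634. Without 1 pool the differences ran from 0.91 to 2.65 for Kcnj8, 1.66 to 4.53 for Mgp, 0.58 to 1.98 for Lum, 0.51 to 1.43 for Gsn, 1.69 to 3.45 for Postn and 0.94 to 2.13 for Bgn. The difference of Lum was 2.56 within number 1 and 0.0018 within number 2. The pericyte median was 1.33 without aged replicate 2, and with the probe set with the largest SD the medians were 1.61 for pericytes, 0.82 for progenitors and 0.65 for matrix genes.

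Immune transcripts moved in both directions. Chemokines and cytokines rose as a list, with 18 of 27 higher and a median of 0.61 (0.17 and 0.50 within numbers 1 and 2; camera adjusted p = 0.0137; adjusted p = 0.312 with an estimated correlation). Beside Ccl5, the neutrophil attractants Cxcl1 (1.49 ± 0.36) and Cxcl2 (1.24 ± 0.38) and the cytokine Osm (1.44 ± 0.37) had the smallest p-values, and Ccl5 alone passed adjusted over the list alone. Macrophage and monocyte markers fell as a list, with 13 of 22 lower and a median of -0.41 (-0.46 and -0.38 within numbers 1 and 2; camera adjusted p = 0.0325; adjusted p = 0.313 with an estimated correlation). Its macrophage genes Adgre1 (-2.42 ± 0.36), C1qa (-2.09 ± 0.50) and Cd163 (-1.41 ± 0.49) were lower, while Ptprc, carried by all leukocytes, stood at 1.94 ± 0.58. Adgre1 alone passed adjusted over the list alone. The list of lymphocyte and granulocyte markers was not called (median 0.34, adjusted p = 0.178, 0.0424 without probe sets ending in _x_at or _s_at and 0.107 to 0.710 under the other settings run), and adjusted over the list alone 2 of its members passed higher, Cd3d and Cd3g, and 2 passed lower, Gzma (-3.90 ± 0.53) and S100a8 (-2.77 ± 0.50), all named for this count after their values were seen. The chemokine call was lost without young replicate 2, aged replicate 1 or aged replicate 2, and the macrophage call without young replicate 1, aged replicate 1 or aged replicate 2. Both were lost on ranks (adjusted p = 0.0592 and 0.0641), the chemokine call also over members held by no other list (0.0526) and the macrophage call with the probe set with the largest SD (0.126). Without 1 pool the differences ran from 1.16 to 2.71 for Ptprc and from -1.93 to -0.89 for Cd163. The chemokine median was 0.39 without young replicate 1 and 0.35 without aged replicate 2, and the macrophage median -0.26 without young replicate 2.

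Growth and protein synthesis lists shifted by small amounts. Cytosolic ribosomal protein genes rose, with 24 of 31 higher and a median of 0.32 (0.40 and 0.26 within numbers 1 and 2; camera adjusted p = 0.0055; adjusted p = 0.312 with an estimated correlation), with the smallest p-values in Rpl12 (3.07 ± 0.54), Rps19 (1.15 ± 0.37), Rpl11 (1.10 ± 0.39) and Rpl10a (0.95 ± 0.39). Cell cycle genes rose, with 24 of 31 higher and a median of 0.27 (0.26 and 0.30 within numbers 1 and 2; camera adjusted p = 0.0387; adjusted p = 0.312 with an estimated correlation). No member had an unadjusted p under 0.05. The smallest p-values were those of Mcm4 at 1.94 ± 0.87, Pcna at 1.08 ± 0.47, Rrm1 at 0.86 ± 0.43 and Tyms at 0.81 ± 0.36. The IGF, insulin and mTOR list fell, with 18 of 25 lower and a median of -0.18 (-0.42 and -0.26 within numbers 1 and 2; camera adjusted p = 0.0445; adjusted p = 0.312 with an estimated correlation). The insulin receptor substrate Irs1 (-2.61 ± 0.41), Foxo4 (-1.52 ± 0.47), the receptor Insr (-1.15 ± 0.37) and Akt2 (-1.01 ± 0.37) had its smallest p-values. Probe sets ran from -2.14 to 0.63 for Insr, -2.56 to -0.21 for Akt2 and -2.82 to -0.22 for Foxo4. Adjusted over the list alone, Rpl12 and Irs1 passed and no cell cycle gene did. With the replicate number as a block the cell cycle call was lost (adjusted p = 0.0508). The cell cycle and IGF calls were lost without young replicate 1, aged replicate 1 or aged replicate 2, the cell cycle call also without young replicate 2, and the ribosomal call without aged replicate 1. With the probe set with the largest SD the cell cycle (adjusted p = 0.126) and IGF (0.189) calls were lost, and the IGF call also with quantile normalization (0.0777), without probe sets ending in _x_at or _s_at (0.0632) and on ranks (0.0509). Without 1 pool the differences ran from 0.62 to 3.26 for Mcm4, whose lowest value was without young replicate 2, 0.57 to 1.58 for Pcna and 0.47 to 1.25 for Rrm1. The cell cycle median was 0.13 without aged replicate 2, and the IGF median was -0.32 without young replicate 2, -0.36 without aged replicate 1 and -0.10 with quantile normalization.

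Camera called none of the remaining lists. Among pathways, the medians and adjusted p-values were 0.20 and 0.407 for Notch, 0.07 and 0.462 for JAK-STAT, 0.26 and 0.462 for TGF-beta and BMP, 0.02 and 0.711 for FGF receptors and feedback, and 0.07 and 0.820 for Wnt. They were 0.26 and 0.178 for heat shock and chaperones, -0.16 and 0.273 for autophagy and lysosome, -0.13 and 0.489 for the antioxidant response, 0.16 and 0.768 for immediate-early and dissociation stress genes, 0.16 and 0.903 for CDK inhibitors and senescence, -0.03 and 0.903 for the interferon response, -0.14 and 0.838 for cell polarity and -0.13 and 0.557 for MHC class II. Among cell types, they were 0.25 and 0.186 for Schwann cells, -0.27 and 0.258 for endothelial cells, 0.35 and 0.398 for adipocytes, 0.02 and 0.729 for erythroid cells and -0.07 and 0.779 for tenocytes. Adjusted over the list alone, the autophagy gene Bnip3 (-2.21 ± 0.37) and the p53 target Ccng1 of the senescence list (-2.44 ± 0.38) passed, both named after their values were seen. In the Wnt list the mean was -0.04, below 0 where the median was above, and in the interferon list it was 0.02, above 0 where the median was below. Many of these medians turned on 1 pool. The median was -0.24 without aged replicate 1 for CDK inhibitors, 0.13 without aged replicate 2 for the antioxidant response, -0.12 without young replicate 2 for immediate-early genes, 0.13 without young replicate 2 for cell polarity, and 0.21 without young replicate 2 for the interferon response. It was 0.03 without young replicate 2 for endothelial cells, -0.22 without young replicate 2 for erythroid cells, 0.33 without aged replicate 1 for tenocytes, -0.04 without aged replicate 2 for FGF and 0.01 without young replicate 1 for autophagy. For TGF-beta and BMP it was -0.14 and 0.58 within numbers 1 and 2, and 0.01 without aged replicate 2. Other medians moved without a change of sign, among them 0.06 for Notch without aged replicate 1 and 0.56 for Schwann cells without aged replicate 2. The sex-linked list had 4 measured genes and was not tested.

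Control probe sets were read beside these comparisons. The 3' minus 5' difference of actin, a sign of RNA integrity and amplification, was 0.30 higher in aged than in young pools, and that of Gapdh was 0.08 lower (a difference of -0.08), with aged 2 at 1.495 and the other arrays between -0.52 and 0.61. The bacterial hybridization controls, added in fixed amounts, differed by number: bioB was higher in the arrays numbered 2 by 1.79, bioC by 1.46, bioD by 0.59 and cre by 0.03, while their aged minus young differences were 0.09, 0.13, 0.10 and -0.01.

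**Figure D3:**
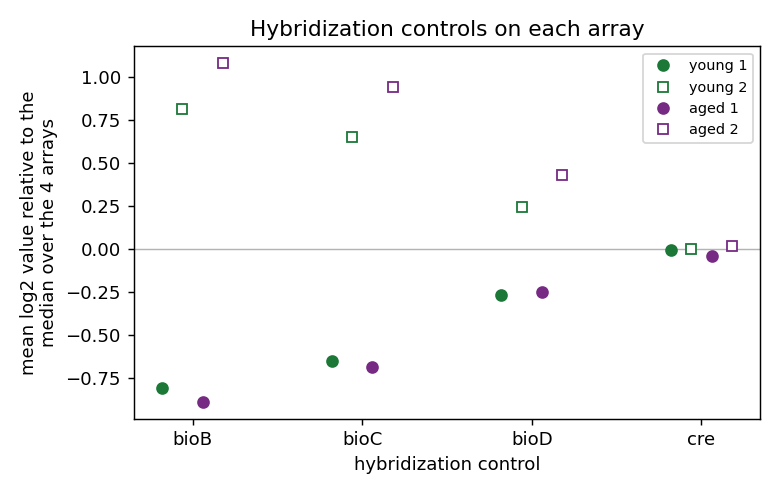
Mean log2 value of each bacterial hybridization control (vertical axis, relative to each probe set's median over the 4 arrays) on each array, with young pools in green, aged pools in purple, filled circles for pools numbered 1 and open squares for pools numbered 2. For bioB, bioC and bioD both arrays numbered 2 lie above both arrays numbered 1, by 1.79, 1.46 and 0.59 on average, and for cre all lie close to 0.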

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

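The bioB hybridization control gave a signal outside the comparison of ages: the arrays numbered 2 read 1.79 higher than those numbered 1 on the log2 scale, while cre differed by 0.03. Young 2 lay 1.62 above young 1 and aged 2 lay 1.97 above aged 1, so the split runs across both ages and each number holds 1 array per age. No explanation was tested for it.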

How the results depend on the processing

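The setting with the largest SD was chosen after the data were seen, as was that with fibre and energy genes left out. The latter removed no member from any other list. With centred values signal over background is unknown. The dim-gene filter, log2 offsets and highest-mean probe set were not run. No gene was called by limma with quantile normalization, a common median, fewer probe sets, the largest SD, all probe sets, treat, array weights or any pool left out; 221 genes were called with trend = TRUE, 39 at an adjusted p under 0.10, and 586 at an unadjusted p under 0.01 with a 2-fold difference. The counts of 113 higher and 473 lower genes became 234 and 812 over all probe sets, more features being tested, and 46 to 160 and 177 to 355 without 1 pool, where the lone pool is assumed to vary like the other age. The 14 called lists became 0 with an estimated correlation and 1 with fry (mature myofibre), which tests each list by itself, and 5 to 12 without 1 pool; under the other settings 10 to 15 were called. The loss of all calls with an estimated correlation can come from the 2 degrees of freedom of that test alone. No called list changed direction under any of these settings. The mature myofibre list was called under all settings but the estimated correlation, and the oxidative phosphorylation, proteasome, glycolysis and fibro-adipogenic progenitor lists under all but the estimated correlation and fry.

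With the replicate block, 0 genes were called (smallest adjusted p 0.303), 87 higher and 414 lower genes had an unadjusted p under 0.01 with a 2-fold difference, and 13 of the 14 lists kept their call; the cell cycle list had an adjusted p of 0.0508. The differences between the pools of each age correlated across genes at 0.138, genes being no independent replicates. The mean correlation within ages exceeded that between ages by 0.32 with Pearson and 0.22 with Spearman. No pair of these centred arrays correlated positively. Pearson correlations were -0.039 between the young pools and -0.031 between the aged pools, and ran from -0.44 to -0.26 between ages.

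Named genes that reversed had small differences, and the cause was not tested beyond fewer samples or probe sets. Without 1 pool the lowest and highest values were -0.35 and 0.58 for Myod1, -0.49 and 0.076 for Sdc3, -0.63 and 0.052 for Cd34, -0.52 and 0.22 for Vcam1, -0.91 and 0.38 for Spry1, -0.52 and 0.024 for Mapk11, -0.43 and 0.26 for Jak2, -0.30 and 0.83 for Stat3, -0.21 and 0.99 for Socs3, -1.70 and 0.36 for Cdkn2a, and -0.91 and 1.24 for Cdkn1b. With the largest SD, Fgfr1 was -0.23, Jak2 0.12, Stat3 -0.71 and Cdkn1b -0.42. Without _x_at and _s_at probe sets, Myod1 was -0.31 and Socs3 -0.21.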

Other observations

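The lists of this part were assembled after the values had been seen, so their p-values describe the data and carry no adjusted call. T cell genes were higher in aged cells in 24 of 26 cases, with a median log2 difference of 1.29 (1.09 and 1.22 within numbers 1 and 2; camera unadjusted p = 7.9e-11, and unadjusted p = 0.0329 with an estimated correlation). Of these 26 genes, 6 also stood in a list fixed beforehand. Of the 26, 12 had an unadjusted p under 0.05 with limma, all of them higher. Outside the fixed lists, the costimulatory receptor Cd28 (2.35 ± 0.60), the interleukin 7 receptor Il7r (1.89 ± 0.38), the coreceptor Cd5 (1.56 ± 0.41) and the adaptor Lat (1.58 ± 0.48) were higher. Zap70 (0.18 ± 0.37), Trat1 (-0.02 ± 0.40) and Cd6 (-0.06 ± 0.51) differed by less than their standard error. Gzma, a granzyme of cytotoxic lymphocytes that this list does not hold, was lower (-3.90 ± 0.53). Genes of B and plasma cells were higher in 9 of 10 cases, with a median of 0.79 (camera unadjusted p = 0.0011, and unadjusted p = 0.0764 with an estimated correlation). Jchain had the largest difference and was the only 1 of the 10 with an unadjusted p under 0.05 with limma. Mzb1 (-0.17 ± 0.43), Pou2af1 (0.16 ± 0.57) and Cd79a (0.29 ± 0.41) differed by less than their standard error. Circadian clock genes were divided, 9 higher and 7 lower, with a median of 0.17 (camera unadjusted p = 0.552). Genes that escape X inactivation had a median of 0.42, with Kdm6a at 1.37 ± 0.51, Ddx3x at 0.73 ± 0.38, Kdm5c at 0.11 ± 0.38 and Eif2s3x at -0.06 ± 0.39.

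Some genes that place cells along the limb were much lower in aged cells, and the test of them was chosen after the results were seen. Hoxd9 stood at -3.98 ± 0.39, Tbx15 at -3.67 ± 0.36, Hoxd8 at -2.84 ± 0.47 and Hoxc10 at -2.81 ± 0.49. Over the 18 measured limb position genes, 13 were lower and the median was -0.23 (camera unadjusted p = 0.0014, and unadjusted p = 0.0745 with an estimated correlation). The list holds Hoxd9, Tbx15, Hoxd8 and Hoxc10 themselves, so these p-values partly restate them. Only 4 of them were far apart, and the others ran from -1.73 (Hoxd10) to 0.71 (Hoxd11), which shows no general loss across the list. Centred values do not show which of these genes were detected, so a loss among detected genes stays open.

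The tests of the lower fibre transcripts were chosen after the results were seen. Mature fibre markers could be lower because the young pools held more fibre RNA, and they fell further than 12 immature muscle genes, by a difference of medians of -1.49 (permutation p = 0.00089). The permutation shuffled genes, which are no independent replicates, so its p does not measure the spread between pools. The immature genes were listed after the values were seen and hold Tnnt1 and Tnni1, which slow fibres also carry. The difference of medians therefore leaves the explanation open. The immature genes were themselves lower, 10 of 12, with a median of -1.34. All 12 belong to the fixed list of myogenic commitment and differentiation. That whole list had 18 of 29 members lower and 11 higher, with a median of -0.49. Because the 12 were chosen after the values were seen, their fall does not decide whether young cells were further along differentiation. Scaling between arrays is an unlikely cause, since the median of the fibre markers was -2.74 after quantile normalization and -2.83 before.

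The tests of Xist were chosen after the results were seen. Female mice in the aged pools and male mice in the young pools could give such a difference. Pools holding mice of both sexes were not considered. The genes that escape X inactivation had a median of 0.42, with 3 higher and 1 lower. The 4 Y-linked genes had a median of -0.012 and ran from -0.09 to 0.52. Centred values do not show whether the Y-linked genes were detected at all, so a difference in sex stays open. A fault of 1 probe set is unlikely, as the smallest of the 3 Xist differences was 5.76. The sex of the mice is not given in the sources used here and would settle the point. If the ages did differ in sex, no difference between ages reported here could be told apart from a difference between sexes.

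The tests of the T cell transcripts were chosen after the results were seen, and that of a smaller fibre share was run in 3 forms, the first dropped because it rested on Cd3d and Cd3g themselves. T cells among the sorted aged cells might raise Cd3d and Cd3g. The other 4 T cell markers of the fixed lymphocyte list were all higher, but only Cd8a (1.43 ± 0.50) by more than its standard error. Cd3e stood at 0.34 ± 0.37, Cd2 at 0.65 ± 0.77 and Cd4 at 0.12 ± 0.40. The median of these 4 markers, 0.50 (SD 0.57), is too small against their spread to settle the point. Of the 26 T cell genes listed after the values were seen, these markers among them, 24 were higher. Gzma was lower, but 1 gene does not decide the point. A smaller share of fibre RNA could instead raise all other cell types alike. The median was 0.71 for pericyte, 0.44 for fibro-adipogenic, -0.27 for endothelial (0.03 without young replicate 2) and -0.41 for macrophage markers. Over the 8 marker lists of cells other than fibres and lymphocytes, the highest median exceeded the lowest by 1.12 (permutation p = 0.0591; 1.504 and 0.999 within numbers 1 and 2), and the median of the 4 T cell markers exceeded that of the 22 macrophage and monocyte markers by 0.90 (permutation p = 0.108). These values lean against an equal rise of all other cells without excluding it. Both permutations shuffled genes, which are no independent replicates, so their p-values do not measure the spread between pools.

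The 4 arrays can be divided into 2 and 2 in 3 ways, so 3 splits cannot give a share under 0.05. The real split had 586 genes with an unadjusted p under 0.01 with limma, the most of the 3 and 1 of 3 with that many. The highest other, the split by replicate number, had 162, and the third had 63.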
